A study of Mus musculus with 2 samples.

How the data were processed

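RNA was measured in 2 libraries of regulatory T (Treg) cells from injured mouse muscle, 1 library per treatment. Per the labels' protocols, 5000 cells per library were sorted in repeated rounds into Trizol, poly(A) RNA was converted to cDNA and amplified, and the cDNA was fragmented with a transposon before paired-end sequencing of 25 bp reads. The labels' protocols name no molecular identifiers, so amplified reads are not independent molecules, and every interval and floor given here covers counting error only.

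The authors deposited a single table of raw counts, whole numbers per gene symbol, for 23337 symbols and both libraries. Per the submitters' processing notes, TopHat2 2.0.10 and Cufflinks 2.2.1 were used with the mm10 mouse genome; what each did, the counting program, the annotation and the treatment of strand are not given in the sources used here. Reads of overlapping genes, of genes on opposite strands, and of near-identical copies (processed pseudogenes of ribosomal protein genes, Hspa1a with Hspa1b, Lyz1 with Lyz2, the Bcl2a1 family) could therefore be split or lost in ways that cannot be checked from the table. Each column was tied to its library by its name, 0 columns were left unused, and 0 rows lacked a gene name.

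Levels are given as CPM, the count of a gene scaled to a common library total. The deposited counts summed to 4080791 in the IL-33 library and 1573707 in the PBS library, a ratio of 2.59. A single count equals 0.245 CPM in the IL-33 library and 0.635 CPM in the PBS library. A count of 0 allows a level of up to 3 counts, which is 0.735 CPM and 1.91 CPM.

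From the counts, CPM values were computed by dividing by the library total. Genes with at least 5 CPM in at least 1 library were compared. The log2 fold of IL-33 over PBS was taken on CPM plus a pseudocount of 1, a scale that understates differences of low genes, and genes were counted as higher or lower at 2-fold or more. Ratios of CPM are given without the pseudocount, with the exact conditional (Clopper-Pearson) 95% interval. Where a gene had 0 counts in 1 library, the fold is a lower bound against 3 counts in that library and is written as "at least". The lower limit of the exact interval, which also counts the error of the other library, is lower still, for Plk4 25.2 in place of 31.2. With 1 library per group there was no test, no p-value and no standard error. In their place, each gene's log2 fold was set beside those of the 200 genes nearest to it in mean CPM. The value given is the percent of those genes at least as far from 0 in either direction. This describes these 2 libraries and does not measure variation between mice. A call at 2-fold does not place a gene outside this scatter. The percent was 1.5 for Ccr1 and 4 for Rel, but 15 for Themis, 22 for Myc and 32.5 for Nfkb2.

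Before the data were examined, 35 gene lists were fixed, 24 for the studied cells, the treatment, RNA quality and scaling and 11 for other cell types, together with the rule for naming genes, the floor, the threshold and the first set of alternatives. Of the 743 symbols fixed, 736 were in the table. For each list with at least 5 members over the floor (28 lists), the median log2 fold of its members was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list was called outside the random lists when its percentile was under 2.5 or over 97.5, so 1.4 of the 28 lists would lie outside by chance. The genes named are the 15 with the highest and the 15 with the lowest log2 fold among genes with at least 10 CPM in a library (predicted models, short RNAs and repeated families left out), the 4 members of each study list farthest from 0, the 2 highest-expressed markers of each other cell type, and 13 fixed genes. A few genes that this rule takes are not reported here. Any other gene is said to have been chosen after its values were seen.

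Gene positions, types, transcript lengths and GC content were taken from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names. Of the 23337 symbols, 20892 matched by symbol, 1913 by an older name and 532 not at all. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for trimmed mean of M-values (TMM) scaling factors alone.

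The computation was tested on simulated data drawn at the depths of the IL-33 and PBS libraries, with 200 genes changed by known folds among 8571 genes. The changed genes were drawn from those with a mean of 20 CPM or more. Of the genes simulated 2.8-fold higher, 98% were counted as 2-fold higher, and of those simulated 2.8-fold lower, 4-fold higher or 4-fold lower, 100% were recovered. Counting noise alone put 1.05% of 8356 unchanged genes at 2-fold or more, and 0% of the 3381 with a mean of 50 CPM or more. The exact intervals held the true ratio for 94.9% of 2000 unchanged genes with a mean of 50 CPM or more. Recovery below 20 CPM and interval coverage below 50 CPM were not checked. Of 26 unchanged lists, 1 fell outside the random lists. These simulations hold no amplification noise, no difference between mice and no shared variation of the members of an unchanged list.

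Alternatives were pseudocounts of 0.1 and 5 CPM, no floor or a floor of 20 CPM, thresholds of 1.5-fold and 3-fold, the exact interval beyond 2-fold, scaling by the median, the upper quartile or TMM, the mean in place of the median of a list, and lists without shared members or without the member farthest from 0. Added after the data were seen were thinning the IL-33 library to the PBS total, floors of a mean of 50 or 100 CPM, removal of genes at 0 in 1 library, and random lists matched also on transcript length or GC content.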

Results

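Gene expression was profiled in Treg cells, the Foxp3-expressing CD4 T cells that restrain immune responses, taken from skeletal muscle after injury. The mice were 8-week-old males of a C57BL/6 strain in which a green fluorescent reporter marks Foxp3 expression. Muscles were injured with cardiotoxin, a snake toxin that kills muscle fibres, and were given either 0.3 ug of recombinant IL-33 or PBS into the muscle, and Treg cells were sorted 4 days later. IL-33 is a cytokine released by damaged tissue, and its receptor is encoded by Il1rl1. The design asks how the muscle Treg transcriptome differs with added IL-33. Each group held 1 library, so no difference given here has a replicate check, and "higher" and "lower" compare the 2 libraries, not the treatments. The IL-33 library held 4080791 counts over 11068 genes above 0, and the PBS library 1573707 counts over 9763 genes. In both, 11808 of the listed genes were at 0.

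Abundant genes differed little between the libraries, and the Treg genes Ctla4, Icos and Ikzf2 were at closely similar levels (Icos was chosen after its values were seen). The IL-33 library had 1.44 to 1.56 times the PBS level of the IL-33 receptor gene Il1rl1, the growth factor gene Areg and the receptor gene Klrg1. By distance from 0 in either direction, these lay within the scatter of genes of like expression, of which 6.5% to 16% were as far. Genes of oxidative phosphorylation were higher as a group in the IL-33 library. So were cytosolic ribosomal protein genes, though not against lists matched on transcript length (percentile 61.9). Mitosis genes were also higher, though not among well-counted members (percentile 94.0) or with 1 high member, Cdca8, left out (96.5). The list of IL-2 and STAT5 targets, which also holds genes of the pathway itself, was lower in the IL-33 library. By the mean over members it lay inside the random lists (percentile 8.37). A few low-level markers of dendritic cells were lower as a group, as were those of monocytes and macrophages, the latter not at a floor of 20 CPM (percentile 4.14). Fibroblast markers were lower by median and by mean, though the median lay inside the random lists with Col3a1 left out (percentile 11.4). Among these lists, the interval of the median over members left out 0 for oxidative phosphorylation and ribosomal protein genes alone. Of 9005 genes over the floor, 1399 (15.5%) were at least 2-fold higher in the IL-33 library, 1466 (16.3%) at least 2-fold lower, and 6140 (68.2%) within 2-fold. Most of these differences lay among thinly counted genes: 68.5% of the 1928 genes with a mean of 2.5 to 10 CPM differed by 2-fold or more, against 2.22% of the 990 genes with a mean of 200 CPM or more. The SD of the log2 fold was 2.23 in the first of these ranges and 0.42 in the second. Of the genes counted as higher, 426 had 0 counts in the PBS library, and of those counted as lower, 177 had 0 counts in the IL-33 library. The median log2 fold was -0.08, and scaling by TMM adds 0.12 to every value, so genes and lists nearer to 0 than this have no settled direction.

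**Figure D1:**
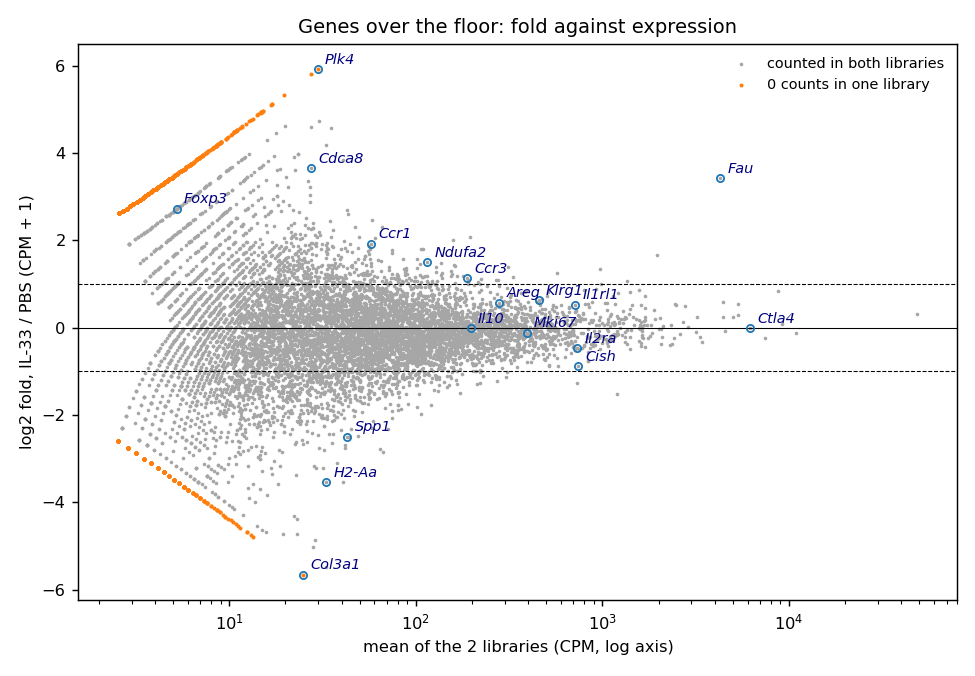
Log2 fold of IL-33 over PBS (CPM plus 1, vertical axis) against the mean of the 2 libraries (CPM, log axis) for 9005 genes over the floor. Grey points were counted in both libraries, orange points had 0 counts in 1 library, dashed lines mark 2-fold, and labelled circles are genes named in the text; the spread narrows from an SD of 2.23 at a mean of 2.5 to 10 CPM to 0.42 at 200 CPM or more.

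The 15 genes with the highest log2 fold all had 0 counts in the PBS library. Plk4, the kinase that starts centriole duplication, led with 243 counts in the IL-33 library, at least 31.2-fold higher (chromosome 3, 40800019 to 40816883). The kinase gene Riok2 had 225 counts and was at least 28.9-fold higher, and Cdc25a, a phosphatase that drives entry into S phase, had 139 counts and was at least 17.9-fold higher. Pparg, a nuclear receptor known from fat-tissue Treg cells, had 122 counts and was at least 15.7-fold higher (chromosome 6, 115360951 to 115490399). The others were Slc33a1, Muc1, Pepd, Paqr8, Tsen34, Hsd17b7, Dkk3, Lonrf1, Hsdl2, Zfp672 and Gmpr2. The 15 genes with the lowest log2 fold all had 5 counts or fewer in the IL-33 library. Col3a1, a fibrillar collagen gene, had 0 counts there and 78 in the PBS library, at least 67.4-fold lower (chromosome 1, 45311538 to 45349706). Fam193b had 2 counts against 103, a PBS to IL-33 ratio of 134 (95% counting interval 36.0 to 1117). Vcl, which encodes the adhesion protein vinculin, had 0 counts against 41 and was at least 35.4-fold lower. The others were Naa40, Urb1, Atp6v1g2, Zbtb24, Phxr4, Btbd11, Tex15, Ttc17, Zfp189, Trub1, Fam122b and Kcnj15. None of these highest and lowest genes reached a mean of 50 CPM.

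Genes of Treg identity differed little. Ctla4, an inhibitory receptor, stood at 6186 CPM in the IL-33 library and 6246 CPM in the PBS library, and Ikzf2, the transcription factor Helios, at 1681 and 1925 CPM. Il2ra, the high-affinity IL-2 receptor chain, was at 613 against 851 CPM, a ratio of 0.721 (0.674 to 0.771), and 16.5% of genes of like expression lay as far from 0. Foxp3 itself was thinly counted, with 40 counts in the IL-33 library and 1 in the PBS library, a ratio of 15.4 whose interval ran from 2.61 to 624. Of the 21 members of the Treg identity list over the floor, 18 were within 2-fold, 2 were higher (Foxp3 and Tigit) and 1 was lower (Rgs16). The list median was -0.20, at percentile 16.0 of the random lists. The T cell receptor complex list had a median of 0.03 (percentile 77.2), with 19 of 20 members within 2-fold and Themis, a signalling protein of T cell development, lower at 0.310 (0.196 to 0.489). Cd4 was at 543 and 526 CPM, and Cd3e, with 77 and 19 counts, at 18.9 and 12.1 CPM. Inhibitory and costimulatory receptors had a median of -0.27 (percentile 8.60), with Tigit and Cd40lg higher and Btla lower among 19 members.

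Genes tied to the IL-33 response and to tissue Treg cells split. Il1rl1 was at 843 CPM in the IL-33 library and 584 CPM in the PBS library, a ratio of 1.44 (1.34 to 1.55; chromosome 1, 40429570 to 40465415). Areg, which encodes the repair factor amphiregulin, was at 334.5 and 224 CPM, a ratio of 1.49 (1.33 to 1.68; chromosome 5, 91139599 to 91148432). Klrg1, a receptor of differentiated effector cells, had a ratio of 1.56 (1.42 to 1.71). Of genes of like expression, 11.5% lay as far from 0 in either direction as Il1rl1, 16% as far as Areg and 6.5% as far as Klrg1. These shares do not rank the 3 genes among higher genes alone. Il10, the suppressive cytokine, was at 195 and 198 CPM, and Gata3, a transcription factor of type 2 and tissue Treg cells, was at 248.5 and 313 CPM, a ratio of 0.795 (0.713 to 0.887). The tissue Treg effector list had a median of -0.05 (percentile 58.4), and 24 of its 26 members were within 2-fold. Its other members, Pparg and Ebi3, were higher, and Ebi3, a cytokine subunit, had a ratio of 3.09 (1.76 to 5.83) on 112 and 14 counts. Of genes of like expression, 1% lay as far from 0 as Pparg and 15.5% as far as Ebi3. Nfil3, at 1.66, and Plin2, at 0.615, were the list's next members by distance from 0.

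Signalling downstream of the IL-33 receptor showed no common direction. The list of receptor and MyD88 signalling genes had a median of -0.12 (percentile 41.4), with 2 members higher, 3 lower and 10 within 2-fold. Irak2, a kinase of the pathway, was higher at 3.41 (2.23 to 5.44), while the ubiquitin ligase gene Traf6 was lower at 0.406 (0.303 to 0.546) and the kinase gene Ikbkb at 0.427 (0.347 to 0.526). Irak3 had 21 counts against 1, a ratio of 8.10 (1.30 to 335), and the receptor partner Il1rap had 57 against 28, a ratio of 0.785 (0.491 to 1.28). Of genes of like expression, 10.5% lay as far from 0 as Irak2, 16% as far as Traf6, 6.5% as far as Ikbkb and 94% as far as Irak3. NF-kB target genes had a median of -0.20 (percentile 23.1), with 0 higher and 3 lower of 23: Rel at 0.431 (0.358 to 0.519), Nfkb2 at 0.363 (0.217 to 0.606) and Zc3h12a at 0.467 (0.297 to 0.737). Nfkbib had 29 counts against 5, a ratio of 2.24 (0.856 to 7.40). Immediate early genes, which follow stimulation or cell handling within minutes, had a median of -0.21 (percentile 14.2). Myc was higher at 2.34 (1.59 to 3.54), and 4 of the 22 members were lower, among them Jun at 0.344 (0.244 to 0.486), Ier2 at 0.444 and Klf2 at 0.449. Type 2 cytokines and receptors had a median of -0.10 (percentile 38.9). Of their 9 members, Il17rb (29 counts against 0, at least 3.73-fold) and Il9r (26 against 0, at least 3.34-fold) were higher and 0 were lower. Il4 and Il13 had 0 counts in both libraries, and Il5, under the floor, had 10 counts in the IL-33 library and 0 in the PBS library.

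The list of IL-2 and STAT5 targets was lower as a group in the IL-33 library. It also holds genes of the pathway itself, such as Jak3 and Stat5a. Its median was -0.50 over 18 members, against -0.40 to 0.26 for the central 95% of random lists (percentile 0.55). The interval of that median over members ran from -0.875 to 0.009 and so held 0. Cish, a feedback inhibitor of cytokine receptors, was at 521 CPM against 956 CPM, a ratio of 0.545 (0.510 to 0.582; chromosome 9, 107296026 to 107302784), and 3% of genes of like expression lay as far from 0. The well-counted survival genes Mcl1 (369.5 against 607 CPM) and Pim1 (324 against 467 CPM), chosen after their values were seen, were also lower. At 2-fold, 3 members were lower: Lif (0 counts against 23, at least 19.9-fold), Osm at 0.294 (0.143 to 0.591) and the kinase gene Jak3 at 0.321 (0.168 to 0.607). Bcl2, with 61 counts against 0, was at least 7.84-fold higher. Stat5a, also chosen after its values were seen, had a log2 fold of 0.58. The mean over members was -0.43, which lay inside the random range at percentile 8.37.

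Mitosis genes were higher as a group in the IL-33 library, with a median of 0.52 over 28 members (percentile 99.6), 11 of them higher at 2-fold and 4 lower. The interval of that median over members ran from -0.049 to 1.691 and so held 0. Cdca8, a chromosomal passenger protein gene, had 210 counts against 5, a ratio of 16.2 (6.83 to 50.4), and Cdk1, the kinase that drives entry into mitosis, had 136 against 4, a ratio of 13.1 (5.01 to 48.8). Bub1 (31 counts against 0) was at least 3.98-fold higher and Kif20a (24 against 0) at least 3.08-fold higher. Mki67, the usual marker of cycling cells, stood at 378 CPM against 409 CPM, a ratio of 0.926 (0.844 to 1.02). Without Cdca8 the list median was 0.35, at percentile 96.5 and so inside the random range. Leaving out any other member above the median gives the same value, so this is no reliance on Cdca8 alone. The mean over all members was 0.71 (percentile 99.8). Over the 9 members with a mean of 50 CPM or more the median was 0.23, at percentile 94.0. DNA replication genes had a median of -0.26 (percentile 15.7) and a mean of 0.30, with 5 higher and 5 lower of 30. Their members farthest from 0 were thinly counted: Cdc45 (74 counts against 0, at least 9.51-fold), Cdc6 (66 against 0, at least 8.48-fold), Gins2 (45 against 0, at least 5.78-fold) and Orc1 (59 against 1, a ratio of 22.7 with an interval of 3.93 to 914).

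Among migration and helper programmes, no list lay outside the random lists. Chemokine receptors and trafficking genes had a median of -0.02 (percentile 65.0), with 5 higher and 2 lower of 24. Ccr1, a receptor for inflammatory chemokines, was higher at 3.91 (2.78 to 5.64; chromosome 9, 123962124 to 123968692), and 1.5% of genes of like expression lay as far from 0. Itga1 had 33 counts against 0, Ccr9 53 against 2, and Cx3cr1 4 against 16. The Th1 list had a median of 0.04 (percentile 71.7), with Il12rb1 lower at 0.447 (0.325 to 0.615) and Ccl5 at 1.80 (1.33 to 2.47). Il18rap, at 1.93 (0.725 to 6.45), and Il18r1, at 0.780 (0.630 to 0.970), were its next members. The Th17 list had a median of -0.16 (percentile 40.6). Its members Il17a (90 counts against 0, at least 11.6-fold) and Il23r (44 against 0, at least 5.66-fold) were higher, Il1r1 was lower at 0.350 (0.249 to 0.491), and Il6ra stood at 0.622. Interferon-stimulated genes had a median of 0.20 (percentile 95.3), with 7 higher and 2 lower of 26. Bst2 was higher at 2.84 (1.75 to 4.86), Oasl1 (32 counts against 0) and Oasl2 (34 against 0) were higher, and Mx1 was lower at 0.357 (0.277 to 0.459). Their mean of 0.41 lay outside the random range, at percentile 97.7. Naive T cell genes had a median of -0.10 (percentile 40.4), with 4 higher and 4 lower of 16, among them Actn1 (23 counts against 0) and Igfbp4 (1 against 11). Suppressive and repair mediators had a median of 0.12 (percentile 80.5), with 3 higher and 4 lower of 16. Spp1, which encodes osteopontin, was lower at 0.166 (0.117 to 0.234), Pdgfb had 1 count against 22, and Hbegf had 27 against 0.

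Genes of oxidative phosphorylation were higher as a group in the IL-33 library. The median over 37 members was 0.31, above each of the 10000 random lists, whose central 95% ran from -0.26 to 0.09. Of the members, 25 lay above 0, 6 were higher at 2-fold and 0 were lower. Subunits of respiratory complex I led: Ndufa2 at 2.85 (2.30 to 3.58), Ndufb3 at 2.30 (1.88 to 2.84), Ndufv1 at 2.15 (1.45 to 3.28) and Ndufa5 at 2.12 (1.74 to 2.61). Cytosolic ribosomal protein genes had a median of 0.20 over 62 members, also above each of the random lists, with 48 above 0, 2 higher at 2-fold and 0 lower. Rps24 was at 3005 against 941 CPM, a ratio of 3.19 (3.02 to 3.37), and Rpl27 at 810 against 339 CPM, a ratio of 2.39 (2.18 to 2.62). Rpl38, at 1.97, and Rps19, at 1.81, were next. The ribosomal RNA precursor Rn45s took 0.532% of counts in the IL-33 library (Wilson 95% interval 0.525 to 0.539) and 0.356% in the PBS library (0.347 to 0.365). The nuclear RNA Malat1 took 5.41% (5.39 to 5.43) and 4.37% (4.34 to 4.40); both were chosen after their values were seen. The oxidative phosphorylation and ribosomal protein lists hold short transcripts, with median lengths of 1062 and 992 nt. Across the 3537 genes with a mean of 50 CPM or more and an annotated length (99.2% of those at that level), which are not independent replicates, the log2 fold was correlated with transcript length (Spearman rho -0.20) and had a median of 0.10 in the shortest of 5 groups of equal number and -0.19 in the longest. Against random lists matched closely on transcript length, oxidative phosphorylation genes lay at percentile 98.3 and ribosomal protein genes at 61.9, inside the random range.

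Other metabolic and stress lists lay inside the random lists. Glycolysis genes had a median of -0.07 (percentile 46.5), with Slc2a1, the main glucose transporter gene, higher at 3.31 (2.00 to 5.84) and Slc16a3 (24 counts against 1) at 9.26 (1.51 to 381). Of genes of like expression, 17% lay as far from 0 as Slc2a1 and 82.5% as far as Slc16a3. The hexokinase genes Hk1, at 0.678 (0.422 to 1.11), and Hk2, at 0.679 (0.388 to 1.22), did not differ beyond counting error. Cholesterol synthesis genes had a median of 0.04 (percentile 68.9), with 4 higher and 0 lower of 21. Among those higher, Hsd17b7 and Mvk had 0 counts in the PBS library, and Sqle had 38 counts against 2, a ratio of 7.33 (1.89 to 62.7). Unfolded protein response genes had a median of -0.35 (percentile 3.48), with 3 of 20 lower: Asns at 0.141 (0.0639 to 0.290), Creld2 at 0.410 (0.286 to 0.588) and Trib3 (3 counts against 10) at 0.116 (0.0205 to 0.449). Sdf2l1 stood at 0.511 (0.327 to 0.805). Heat shock genes, a sign of cell handling, had a median of -0.27 (percentile 11.4), with Bag3 lower at 0.363 (0.263 to 0.499), Hspa1b and Hspa1a lower on 1 against 20 and 0 against 8 counts, and Hsf1 higher on 55 against 0. Common reference genes had a median of 0.08 (percentile 86.0). Cd52 stood at 2.00 (1.87 to 2.14), B2m at 1.46 and Ppia at 1.43.

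**Figure D2:**
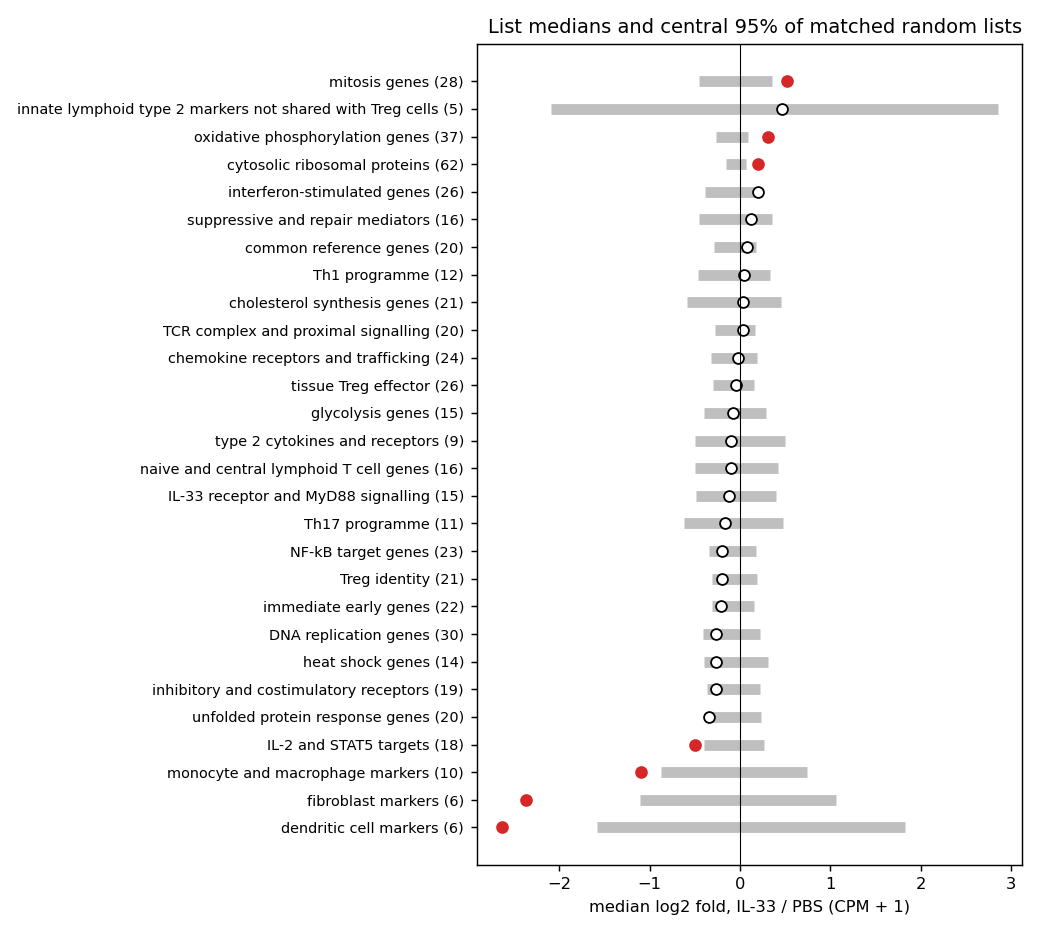
Median log2 fold of IL-33 over PBS (horizontal axis, CPM plus 1) for the 28 lists with at least 5 members over the floor, with the number of members in brackets. Grey bars span the central 95% of 10000 random lists matched on expression; filled red points lie outside it (7 lists, 3 above and 4 below) and open points inside.

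**Figure D3:**
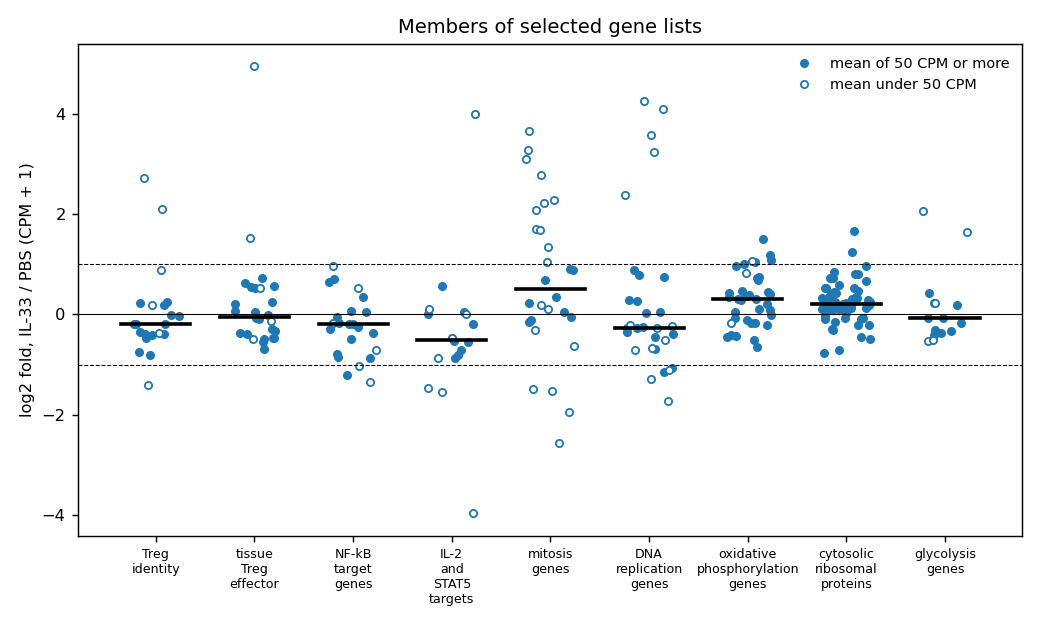
Log2 fold of IL-33 over PBS (vertical axis, CPM plus 1) of each member of 9 lists. Filled points have a mean of 50 CPM or more, open points less, bars are list medians and dashed lines mark 2-fold; most members beyond 2-fold in the mitosis and DNA replication lists are open points.

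Markers of other cell types were scarce in both libraries, and several class II, macrophage and collagen genes were higher in the PBS library. Of 152 such markers in the table, 43 were over the floor and 77 were at 0 in both libraries. Together they made up 0.211% of the counts in the IL-33 library and 0.224% in the PBS library. At 2-fold, 17 were lower and 6 higher in the IL-33 library. The dendritic cell list had a median of -2.64 over 6 members (percentile 0.06), of which 4 were lower at 2-fold and 1 was higher. Its class II genes H2-Aa (18 counts against 97, a ratio of 0.0716 with an interval of 0.0407 to 0.119) and H2-Eb1 (10 against 42) were lower. Monocyte and macrophage markers had a median of -1.09 over 10 members (percentile 0.71), with Ctss, which lymphoid cells also express, at 0.717 (0.661 to 0.777) and Lyz1 at 0.425 (0.321 to 0.563). At a floor of 20 CPM this list lay inside the random range, at percentile 4.14. The macrophage genes Fcer1g, Cd68, Csf1r, C1qa, C1qb and C1qc, under the floor, together with Cd74 had 15 counts in the IL-33 library and 5 in the PBS library. Fibroblast markers had a median of -2.37 over 6 members, or -2.55 with genes at 0 set to their bound (percentile 0.01). Without Col3a1 the median was -0.72 at percentile 11.4, inside the random range. Col3a1 was not alone, since 3 of the 6 members were lower at 2-fold, and the mean over all members was -2.39 (percentile 0.01). The interval of the median over members held 0 for each of these lists. It ran from -3.709 to 1.792 for dendritic cells, -2.905 to 0.435 for monocytes and macrophages, and -5.66 to 0.455 for fibroblasts. Ly6a, which T cells also express, was at 1.37 (1.27 to 1.48).

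The remaining lists of other cells gave no call. Markers of innate lymphoid type 2 cells had a median of 0.46 over 5 members (percentile 54.2), with Bmp7 at 1.29 (0.859 to 2.00) and Hpgds at 0.752 (0.428 to 1.36). The other 7 lists had fewer than 5 members over the floor. Neutrophil markers had a median of -0.59 over 4 members, with Mmp9 higher at 2.66 (1.88 to 3.86) and Cxcr2 at 0.532 (0.352 to 0.812). Among eosinophil and mast cell markers Ccr3 alone was over the floor, at 259 against 118 CPM, a ratio of 2.21 (1.89 to 2.59), while Epx and Cpa3 had 0 counts in both libraries. B cell markers had a median of 0.32 over 3 members, with Cd79b at 1.26 (0.866 to 1.88) and Blk on 26 against 1 counts. CD8 T cell and NK cell markers had a median of -0.50 over 2 members, Cd8b1 at 1.62 (0.995 to 2.74) and Ccl4 at 0.279 (0.151 to 0.507). Myofibre markers had a median of -0.53 over 2 members, Ttn at 0.799 (0.698 to 0.915) and Mylpf at 0.546 (0.246 to 1.25). Endothelial markers had a median of -1.05 over 2 members, Pecam1 at 1.08 (0.816 to 1.43) and Cdh5 on 3 against 11 counts. Erythroid markers had a median of -1.82 over 2 members (-1.97 at the bound), Bpgm at 0.788 (0.610 to 1.02) and Alas2 on 0 against 14 counts.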

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

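The alternatives with floors of a mean of 50 or 100 CPM, thinning, removal of genes at 0 in 1 library, and matching on length or GC content were chosen after seeing the data. No paired analysis was possible because each group held 1 library. The number of genes at least 2-fold higher in the IL-33 library, 1399, became 2133 with no floor, 595 at a floor of 20 CPM, 2116 at 1.5-fold, 909 at 3-fold, 789 when the exact interval had to lie beyond 2-fold, and 50 at a mean of 100 CPM or more. The number of genes at least 2-fold lower in the IL-33 library, 1466, became 737 at a floor of 20 CPM, 2465 at 1.5-fold, 744 at 3-fold, 758 with the exact interval, and 53 at a mean of 100 CPM or more. Fewer or more genes entered under the floors and thresholds by construction. Under the other alternatives for these counts (pseudocounts, scalings, thinning, and genes counted in both libraries) each number stayed within 1.5 times its main value. Of 436 list medians under alternatives, 433 stayed within the interval of the main median over its members, 3 moved outside it, and 0 lists outside the random lists changed sign. The 3 were these: the DNA replication list was 0.30 as a mean, and the ribosomal protein list was 0.295 with upper-quartile scaling and 0.32 with TMM. Staying inside was a weak check, since several intervals were wide, such as -5.66 to 0.455 for fibroblast markers and -0.049 to 1.691 for mitosis genes. Medians of -0.72 for fibroblast markers without Col3a1 and 0.23 for mitosis genes at a mean of 50 CPM counted as staying. Both lists lost their call under those alternatives. The number of lists outside the random lists, 7, was 3 at a floor of 20 CPM and 3 at a mean of 50 CPM or more: IL-2 and STAT5 targets, oxidative phosphorylation and ribosomal proteins in both cases. Mitosis genes lost their call under both and monocyte and macrophage markers under the floor of 20 CPM, and the cause was not tested. Dendritic cell and fibroblast markers under both, and monocyte and macrophage markers at a mean of 50 CPM, had fewer than 5 members left and could not be placed. Of 1258 values of the 150 named genes under alternatives, 1128 stayed within their counting interval, 130 moved outside it, and 0 genes counted at 2-fold changed sign. Ctla4, Il10 and Mki67, close to 0, changed sign under TMM. Depth limits the PBS library more, where 5 CPM is 7.87 counts, against 20.4 in the IL-33 library.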

Other observations

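The tests on fibroblast genes and on antigen-presenting and myeloid genes, the close matching on transcript length, and the genes of the next paragraph other than Ccr1 and Ccr3 were chosen after the results were seen. The other tests were written down before their results were seen, although the short-transcript pattern had been noticed by eye.

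Among the 2044 genes with a mean of 100 CPM or more, 50 were at least 2-fold higher and 53 at least 2-fold lower in the IL-33 library. Fau, which encodes a ubiquitin-like protein fused to ribosomal protein S30, was at 7805 CPM against 726 CPM, a ratio of 10.7 (10.1 to 11.4; chromosome 19, 6057844 to 6059524), and 0% of genes of like expression lay as far from 0. Atox1, a copper chaperone gene, followed at 4.06 (3.30 to 5.04). Crip1 (2.12), Ctsd (2.23), Slc3a2 (2.32) and Serpinb1a (2.66) were also higher by ratio. Lower genes included Cerk at 0.252 (0.207 to 0.306), Zfp36l2, an mRNA decay factor gene, at 0.415 (0.388 to 0.444), and Bhlhe40 at 0.459 (0.413 to 0.510). The ribosomal protein genes Rpl41, at 2.53, and Rpl35a, at 0.349, which the fixed list does not hold, lay on opposite sides of 1, while 48 of the list's 62 members were above 0 on the log2 scale. The neighbouring chemokine receptor genes on chromosome 9 also differed, with Ccr1 at 3.91, Ccr3 at 2.21 and Ccr2 at 1.45. Rpl26 and Rps27, which dividing cells need, had 0 counts in both libraries, so a 0 in this table does not by itself show absence of a transcript.

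In all, 111 genes had at least 50 counts in 1 library and 0 in the other, 110 of them in the IL-33 library. Sampling at the depths of the libraries would give 1.17e-05 such genes, which argues against lower PBS depth as the whole cause. After thinning the IL-33 library to the PBS total, genes with at least 20 counts in 1 library and 0 in the other numbered 107 and 75 in the 2 directions, a ratio of 1.43, and the highest mean among them was 32.7 CPM. Such a pattern in both directions at low expression is what loss of low-copy transcripts before or during amplification may give. The 15 highest genes of the report, the 7 of its 15 lowest genes that had 0 counts in the IL-33 library, and Il17a, Cdc45, Cdc6 and Gins2 had means under that value, and a difference in treatment stays open for each of them.

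Oxidative phosphorylation and ribosomal protein genes were higher in the IL-33 library, as were short transcripts in general. For ribosomal protein genes, the percentile among random lists matched closely on transcript length was 61.9 (81.0 with length in 5 bins). A difference in how the libraries captured short transcripts may therefore account for their median. Ribosomal protein genes outside the list, such as Rpl41, were not removed before matching, so this cannot separate length from a shift of that family. For oxidative phosphorylation genes the percentile was 98.3 (99.7 in bins). Their median was 0.32 over 36 members against an upper random limit of 0.30, which argues narrowly against length as the whole cause. Matching on GC content left both lists at percentile 100, which argues against GC content. The shares of Rn45s (0.532% against 0.356% of counts) and Malat1 (5.41% against 4.37%) were also higher in the IL-33 library, and treatment, RNA quality and other differences between the libraries remain open.

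Col3a1 and class II genes were higher in the PBS library, although cells were sorted repeatedly for the Foxp3 reporter. Of the 6 fibroblast markers over the floor, 3 were lower in the IL-33 library at 2-fold. The median of these markers lay inside the random lists once Col3a1 was left out (percentile 11.4). In the PBS library Col3a1 had 78 counts, while Col1a1, Col1a2 and Sparc, abundant in fibroblasts, summed to 0% of that. This would argue against whole fibroblasts only if those genes could be counted, which was not tested. The lower fibroblast markers other than Col3a1 were not part of this comparison, so whole fibroblasts stay open. Class II genes had 158 counts in the PBS library, while Cd74, Fcer1g, Cd68, Csf1r, C1qa, C1qb and C1qc summed to 3.16% of that. Cd74 had 0 counts in both libraries and holds a microRNA gene at its end, so it may not have been counted, and antigen-presenting cells and RNA taken up from other cells cannot be told apart here.

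The low Foxp3 count in cells sorted for a Foxp3 reporter led to the hypothesis that reads at its 3' end were lost to an overlapping gene. Of the last 500 exonic bases, 19.2% lay in exons of another protein-coding gene, and genes overlapped over most of that stretch were at 0 in both libraries in 34.2% of 840 cases, against 47.0% of 19384 other protein-coding genes. The value of 19.2% argues against overlap as the whole cause, since most of that stretch of Foxp3 lay outside such exons. The second comparison was not matched on expression, so it cannot show how many reads overlap removes. Ccdc22, the gene that overlaps Foxp3 there, itself had 0 counts in both libraries, so its reads may have been lost at this locus. Rpl26, Rps27 and Cd74 were also at 0 in both libraries, so the 0 of Ccdc22 cannot decide whether overlap was the cause. How reads of the reporter transcript itself were counted was not tested.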
